A study of Mus musculus with 8 samples.

How the data were processed

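RNA from GHMT-transduced tail-tip fibroblasts was measured on Clariom S Mouse arrays, 1 biotin-labelled total RNA sample per array, in 8 cultures. Per the labels' protocols, the compound or vehicle was added together with the retroviruses; compound names other than diclofenac and PGE2, doses and the time of harvest are not given in the sources used here. The deposited values are log2 expression values made by the authors: per the submitters' design text, they were normalized with SST-RMA (single space transformation and robust multichip analysis) in Affymetrix Expression Console 1.4. Whether the sets were normalized together is not stated, and the genome build and any filter are not given in the sources used here, so no positions are printed.

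The table held 28846 rows, of which 6640 were control probe sets and 22206 transcript clusters. A gene symbol was joined to 19572 clusters (19505 distinct symbols, 55 of them on more than 1 cluster, where the cluster with the highest mean over all arrays was used for named genes and lists). The other 2634 clusters are unnamed here, not without a gene. The median over the transcript clusters was 5.28 for GHMT, 5.29 for diclofenac, 5.29 for the EP4 antagonist and 5.28 for diclofenac plus PGE2 in set 1, and 5.14 for GHMT, 5.10 for the EP4 antagonist, 5.14 for the TGFb inhibitor and 5.13 for the Wnt inhibitor in set 2. The background level of an array was the 95th percentile of its 23 background probe sets (5.73 to 5.99), a rule chosen after seeing the data. Where the lower arm lay at background in every array, a fold is given as a lower bound against that level ("at least"), and no fold where the bound does not exceed 1. Where only some arrays of the lower arm lay at background, the difference of the means is given as measured.

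Groups followed the labels. The replicate number is the TTF set number attached to the fibroblasts in the titles, and it was used as a block because array correlations were 0.986 to 0.995 within and 0.974 to 0.984 between sets, the first principal component (56.6% of the variance) separated the sets, and the deviations of the GHMT and EP4 antagonist arrays from their group means correlated across genes (r = 0.724). The labels do not say whether replicates are independent experiments, so p-values measure the spread between these samples. The EP4 antagonist was compared with GHMT (2 against 2 arrays), and the arrays with PGE2-EP4 signalling inhibited (diclofenac, EP4 antagonist) with those with it active (GHMT, diclofenac plus PGE2; 3 against 3), by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all transcript clusters, without and with the TTF set as a fixed block. The fit without the block was the main test set beforehand, and the fit with it was an alternative. All standard errors printed are those of the fit with the block. The other contrasts were differences of 1 array from 1 within a set, counted at 2-fold or more. The difference of the EP4 antagonist contrasts of the sets, divided by the square root of 2, served as a reference for the spread of such contrasts.

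Lists of genes were written before the data were examined, as were the groups, tests and the rule for named genes: 26 lists with 591 entries, of which 545 were matched. They cover the transduced factors, cardiac sarcomere, cardiac calcium handling and ion channels, cardiac transcription factors and hormones, oxidative and muscle metabolism, collagens and matrix, fibroblast identity, TGFb response, Wnt targets, prostanoid synthesis and receptors, cAMP and CREB targets, inflammatory cytokines and NF-kB targets, interferon response, cell cycle, p53 targets, integrated stress and unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, and markers of macrophages and leukocytes, endothelium, keratinocytes and epithelium, skeletal muscle, smooth muscle, adipocytes, cartilage and bone, and Schwann and neural cells. Some genes are on more than 1 list. Lists were tested with limma's camera (preset correlation of 0.01, or an estimated correlation) and fry (directional p), adjusted over the lists. Where the block is not named, a list's adjusted p comes from the fit without it, while the counts of list members past the threshold come from the fit with it. In single-array contrasts a list's median was set against 10000 random lists of the same size matched on mean level in 20 bins. Genes were named by rule. For tested comparisons it took the 12 largest rises and 12 largest falls past the threshold without the block, with 1 direction in both sets. As 0 genes passed there, all places were filled by genes with 1 direction in both sets, ranked by the smaller within-set difference. In single-array contrasts the rule took the 10 highest and 10 lowest. The higher arm had to reach the median level, and predicted genes were skipped. In addition, up to 4 members of each list with the largest differences and a fixed set of factor, drug target and marker genes were eligible. List members that passed were named beyond this rule, after their values were seen. Diclofenac plus PGE2 was set against GHMT after seeing the data, and the genes named there were chosen then. Ptgs1, also in the fixed set, is not analysed here.

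On simulated data with 200 changed genes among 22206, drawn with each gene's own moderated spread, the fit without the block recovered 0%, 0%, 64% and 94% of changes of 1, 2, 3 and 4 on the log2 scale for 2 against 2 arrays, and 2%, 60%, 90% and 100% for 3 against 3. With the block it recovered 76%, 100%, 100% and 100% with 11.7% false among the calls, and 88%, 100%, 100% and 100% with 5.83% false. The spread was also drawn from the fitted prior. For 2 against 2 arrays the fit then recovered 0%, 0%, 40% and 76% without the block and 16%, 96%, 98% and 100% with it (10.9% false). For 3 against 3 it recovered 2%, 74%, 90% and 96% without the block and 68%, 100%, 100% and 100% with it (6.12% false). Noise was drawn independently for each gene, so these shares hold for the simulated settings only. In the data, the fit with the block called 0 genes for the EP4 antagonist. There Pde4b was at -3.33 (limma, adjusted p = 0.0777) and Rab3b at 2.96 (0.531). The alternatives were the block, quantile normalization, centring each array on its median, a filter at the 40th percentile of mean level (13324 clusters left), a trend and robust prior, an adjusted p under 0.1, leaving out each array, a threshold of 1.5-fold, the mean of both GHMT arrays as control, a pooled limma fit over all 8 arrays, and 50 or 200 followed genes. Combinations of the block with other settings, set 1 arrays alone, and the mean of both GHMT arrays as control for single genes and lists were chosen after seeing the data. Control probe sets were left out of all tests.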

Results

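The arrays measured RNA from mouse postnatal tail-tip fibroblasts (TTFs) transduced with retroviruses for Gata4, Hand2, Mef2c and Tbx5 (GHMT), cardiac transcription factors used to turn fibroblasts into cardiomyocyte-like cells. Cultures received vehicle, diclofenac (an inhibitor of the cyclooxygenases that make prostaglandins), diclofenac with prostaglandin E2 (PGE2), an antagonist of the PGE2 receptor EP4, a TGFb inhibitor or a Wnt inhibitor. The study asked whether blocking the route from cyclooxygenase-2 over PGE2 to EP4 improves cardiac reprogramming. Of the 8 arrays, 4 were from TTF set 1 (GHMT, diclofenac, EP4 antagonist, diclofenac plus PGE2) and 4 from TTF set 2 (GHMT, EP4 antagonist, TGFb inhibitor, Wnt inhibitor). GHMT and the EP4 antagonist therefore had 2 arrays each, the other groups had 1 each, and untransduced cells were not among the samples. The number of arrays limits the precision, and 43.7% to 45.7% of the 22206 transcript clusters lay above the background level of an array.

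Transcripts of the transduced factors were compared first. Mef2c (17.86 to 19.27 on the log2 scale), Tbx5 (14.25 to 15.16) and Hand2 (11.01 to 12.64) were far above background in all 8 arrays. Within a set, their largest difference from GHMT was -0.67, for Hand2 with the EP4 antagonist in set 2. The Gata4 cluster lay at background in all 8 arrays (3.91 to 4.44); whether its probes cover the transduced Gata4 is not known here, so the factor cannot be compared. The TTF set separated the arrays more than any treatment. Between the GHMT arrays of the sets, 3036 transcript clusters were at least 2-fold apart, 1434 higher and 1602 lower in set 2. Median log2 values were 5.28 to 5.29 in set 1 and 5.10 to 5.14 in set 2. Ptgs2, the gene of cyclooxygenase-2, was at 9.47 to 10.03 in set 1 and at 12.86 in the GHMT array of set 2. Differences are therefore given within a set, or with the TTF set as a block in the fit.

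**Figure D1:**
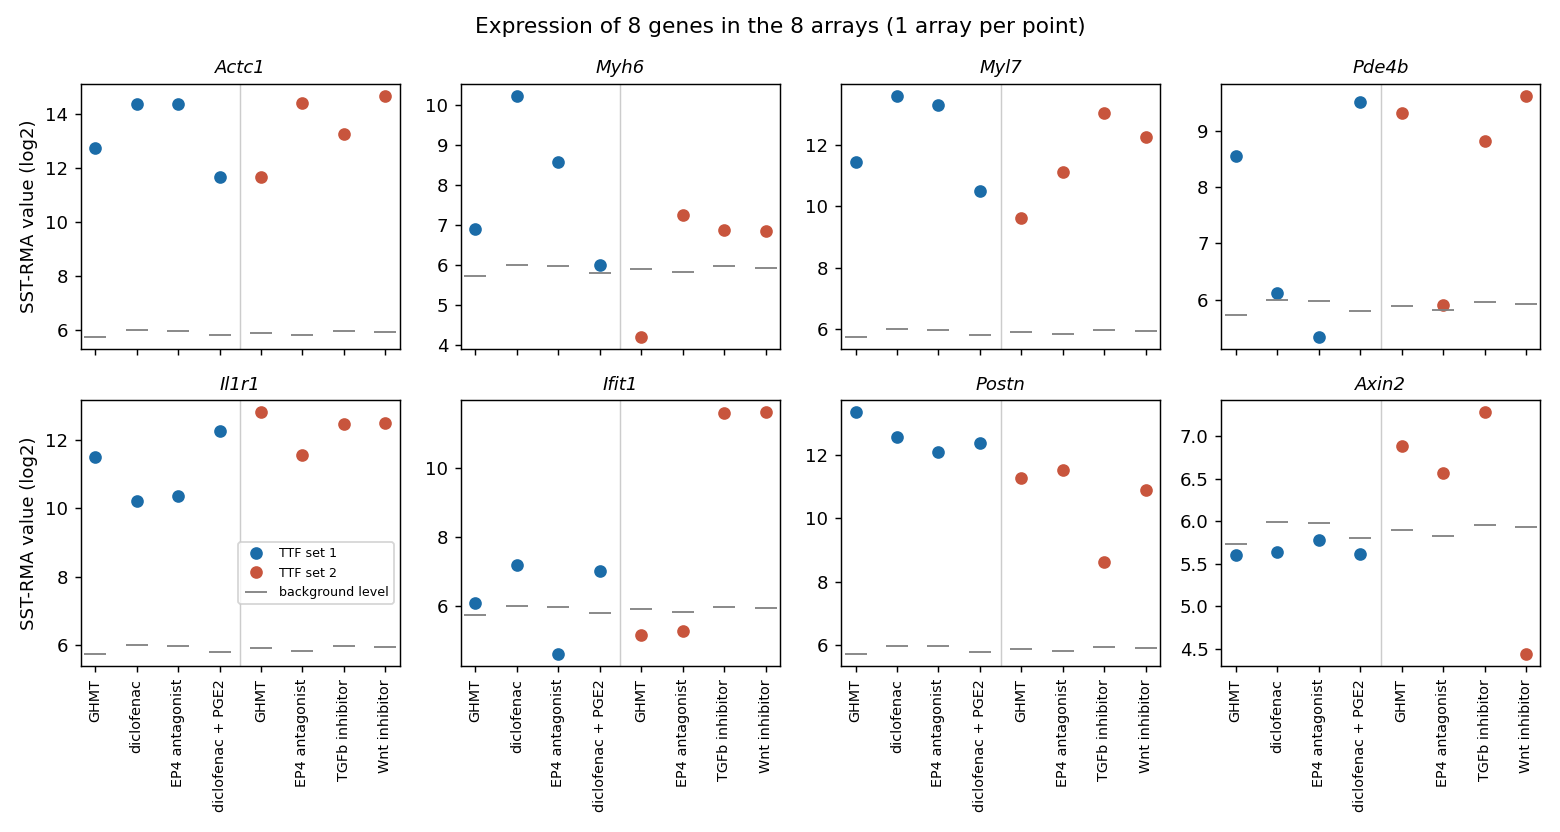
SST-RMA values (log2) of 8 genes in the 8 arrays, with 1 array per point, TTF set 1 in blue, TTF set 2 in red and the background level of each array as a grey dash. Actc1, Myh6 and Myl7 were higher and Pde4b and Il1r1 lower with diclofenac or the EP4 antagonist than with GHMT of the same set, and Ifit1 was highest with the TGFb inhibitor (11.58) and the Wnt inhibitor (11.61).

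The comparison that used most arrays asked what changes when PGE2-EP4 signalling is inhibited (diclofenac, and the EP4 antagonist in both sets; n = 3) rather than active (GHMT in both sets, and diclofenac plus PGE2; n = 3). The arms pool different treatments, which are not replicates of 1 group, so the residual spread includes differences between treatments. Diclofenac plus PGE2 was itself at least 2-fold apart from GHMT of set 1 in 401 transcript clusters. All arrays of set 1 took part, but only GHMT and the EP4 antagonist of set 2. With the TTF set as a block, an alternative to the main test without it, genes of the contractile apparatus rose. Myh6, the alpha-myosin heavy chain of heart muscle, rose by 2.99 ± 0.38 on the log2 scale (SE, adjusted p = 0.0186 by limma), with the GHMT array of set 2 at background. Actc1, cardiac alpha-actin, rose by 2.36 ± 0.26 (5.15-fold), and Myl7, an atrial myosin light chain, by 2.17 ± 0.28 (4.49-fold). Smyd1, a muscle histone methyltransferase, rose by 2.18 ± 0.27. In the opposite direction, Pde4b, a phosphodiesterase that degrades cAMP, fell by 3.35 ± 0.27 (adjusted p = 0.00622), with the EP4 antagonist array of set 1 at background.

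With the set as a block, 84 transcript clusters passed (57 higher, 27 lower; 81 with a gene symbol), and all 84 had the same direction in both sets, which calls from a fit with the block favour by construction. Other genes that rose included Rab3b, a vesicle GTPase (3.16 ± 0.33), Col10a1, a collagen of hypertrophic cartilage (2.85 ± 0.34), Myl1, a fast skeletal myosin light chain (2.22 ± 0.20), Igfbp2 (1.87 ± 0.26), Rrad (1.77 ± 0.17), Flt1, a VEGF receptor (1.57 ± 0.21), and Cspg4 (1.53 ± 0.22). The falls included Mcpt8 (-2.79 ± 0.37), with the diclofenac array and the EP4 antagonist array of set 1 at background. Tgfbi, a matrix protein induced by TGFb (-2.03 ± 0.20), Fbln1, a matrix fibulin (-1.84 ± 0.20), and Prg4 (-1.74 ± 0.27) fell too. So did Slc6a17 (-1.68 ± 0.26) and Il1r1, the interleukin-1 receptor (-1.49 ± 0.21). Large differences that missed the threshold were Stmn2 (2.32, adjusted p = 0.0743), Chl1 (-2.07, 0.0516), Ppbp (-2.09, 0.0995), Erv3 (-2.14, 0.0995), Ptgfr (-2.10, 0.17, at least 1.94-fold), Hsd3b6 (-3.15, 0.172, at least 3.42-fold) and Sod3 (-1.74, 0.442). None of the followed marker genes Gata4 (0.06), Hand2 (-0.33), Mef2c (-0.07), Tbx5 (-0.05), Ptgs2 (0.13), Ptger4 (-0.52), Nppa (0.98), Ryr2 (0.99), Tnnt2 (0.31), Col1a1 (-0.45), Postn (-0.27) and Il1b (-0.16) passed. Without the block, the main test set beforehand, 0 genes passed by limma, and 0 with a trend and robust prior. At an unadjusted p under 0.05 were 469, where 1110.3 would be expected by chance. The smallest adjusted p was 0.068, for Pde4b. With the block, 1925 were under 0.05 unadjusted. The count of 84 changed with the array left out: 192 passed without GHMT replicate 1, 17 without diclofenac plus PGE2 and 4 without EP4 antagonist replicate 1. It was 2 without diclofenac and 0 without either array of set 2. The fits without an array of set 2 are the same, as both rest on set 1 alone. Each leave-out also has fewer degrees of freedom. All 84 kept their sign in each of these fits, which share most of their arrays.

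Camera with its preset correlation called 6 heart and muscle lists up in this comparison, and only that of the sarcomere with an estimated correlation. Of 37 measured cardiac sarcomere genes, 11 lay at background in all 6 arrays, and the other 26 had positive differences (median 1.05, or 0.77 over all 37). With the set as a block, 12 rose over all genes tested and 18 adjusted over the list alone (Myh7, at background, among them), such as Myom1 (1.33), Myom2 (1.27), Mybpc3 (1.26) and Tnnc1 (1.20). The list had adjusted p = 0.0124 with an estimated correlation, and 0.0549, past the threshold no longer, with the block as well. Of 25 genes of calcium handling and ion channels (median 0.34), 1 rose over all genes, Sln, a regulator of the calcium pump (at least 1.35-fold), and 8 adjusted over the list alone, among them Slc8a1 (1.13), Ryr2 (0.99) and Casq2 (0.81). The list had adjusted p = 0.197 with an estimated correlation and 0.149 with the block too. Of 20 cardiac transcription factors and hormones (median 0.12), 3 rose over all genes, Smyd1, Popdc2 (1.56) and Myocd, whose mean of 5.33 in the inhibited arm lay under the background levels, and 4 adjusted over the list alone; adjusted p = 0.185 with an estimated correlation and 0.149 with the block too. Of 25 genes of oxidative and muscle metabolism (median 0.15), myoglobin (Mb, at least 1.67-fold) rose, and 3 rose adjusted over the list alone, with Ppargc1a at 1.15; adjusted p = 0.130 with an estimated correlation and 0.211 with the block too. The 23 skeletal muscle markers, 18 of them at background in all 6 arrays (median 0.07; adjusted p = 0.511 with an estimated correlation and 0.211 with the block too) had Myl1 past the threshold over all genes, and 4 rose and 1 fell adjusted over the list alone, 3 of these 5 at background, with Myh8 at 1.62 and the fallen Tnni2 under the background levels in both arms. Of 15 smooth muscle markers (median 0.18; adjusted p = 0.185 with an estimated correlation and 0.237 with the block too), Ramp1, a receptor subunit for calcitonin peptides, rose (1.98), and 2 rose and 1 fell adjusted over the list alone.

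Fibroblast, cell cycle and inflammatory lists were called down by camera with its preset correlation, and not with an estimated one. Of 32 cell cycle genes, 30 had negative differences (median -0.30); 0 fell over all genes and 3 adjusted over the list alone, Mki67 (-0.60), Bub1b (-0.81) and Mcm6 (-0.59), with adjusted p = 0.185 with an estimated correlation and 0.149 with the block too. Of 13 p53 targets, 11 had positive differences (median 0.34); 0 rose over all genes and 5 adjusted over the list alone, among them Cdkn1a, which halts the cell cycle (0.63), and Mdm2 (0.46); adjusted p = 0.130 with an estimated correlation and 0.146 with the block too. Of 32 collagen and matrix genes (median -0.21), Fbln1 and the proteoglycan Vcan (-1.49) fell over all genes, and 6 fell and 2 rose adjusted over the list alone, with Col3a1 at -0.91 and Dcn at -0.94; adjusted p = 0.185 with an estimated correlation and 0.321 with the block too. Fibroblast identity genes (23, median -0.35) gave 0 over all genes and 7 adjusted over the list alone, 6 of them lower, such as Dpt (-1.76) and Thy1 (-0.76); adjusted p = 0.185 with an estimated correlation and 0.264 with the block too. Of 35 inflammatory cytokines and NF-kB targets, 17 of them at background in all 6 arrays (median -0.13, or -0.26 over the other 18), Il1r1, the protease Mmp3 (-1.63) and Tnfaip6, close to background in both arms, fell over all genes and 4 adjusted over the list alone; adjusted p = 0.130 with an estimated correlation and 0.149 with the block too. Among 23 cAMP and CREB targets (median -0.22), Pde4b fell over all genes, and 4 fell and 2 rose adjusted over the list alone, with Nr4a2 at -1.14 and Pde10a at -1.27; adjusted p = 0.185 with an estimated correlation and 0.321 with the block too. Genes of hypoxia and glycolysis (18, median -0.27; 0 over all genes, 3 adjusted over the list alone, such as Pdk1, which limits mitochondrial pyruvate use, at -0.64; adjusted p = 0.600 with an estimated correlation and 0.211 with the block too) had 15 negative differences, and the 22 Wnt targets (median 0.10; 0 and 0; adjusted p = 0.185 with an estimated correlation and 0.237 with the block too) had 16 positive ones.

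In all, camera with its preset correlation called 14 of the 26 lists, 8 up and 6 down, with and without the block; over the 12 alternatives their adjusted p spanned 4.62e-28 to 0.979. The calls of 6 lists (sarcomere, calcium handling, cardiac transcription factors, oxidative metabolism, cell cycle and p53 targets) were kept whichever array was left out. These leave-outs were without the block, so the TTF sets lay unequally in the arms. Kept and ended calls therefore mix set differences with the dependence on an array. Leaving out GHMT replicate 2 ended those of fibroblast identity (adjusted p = 0.162), cAMP targets (0.268), inflammatory genes (0.162), skeletal muscle (0.268) and hypoxia (0.394). Leaving out GHMT replicate 1 ended those of matrix genes (0.186), Wnt targets (0.139) and smooth muscle (0.186). Without EP4 antagonist replicate 1, matrix (0.124), fibroblast (0.0863) and hypoxia genes (0.323) missed the threshold, without replicate 2 Wnt targets (0.979) and smooth muscle (0.565), without diclofenac hypoxia genes (0.485), and without diclofenac plus PGE2 Wnt targets (0.181) and smooth muscle (0.269). The fry test called 1 list without the block (sarcomere, adjusted p = 0.0209) and 2 with it (sarcomere and p53 targets, both 0.0138). Lists not called were the transduced factors (median -0.06), TGFb response (0.03, with Tgfbi fallen), prostanoid synthesis and receptors (-0.08), interferon response (-0.12), integrated stress and unfolded protein response (0.00), cholesterol synthesis (-0.13), and the markers of macrophages and leukocytes (-0.12), endothelium (-0.03, with Flt1 risen), keratinocytes (-0.06), adipocytes (0.04), cartilage and bone (-0.09, with Col10a1 risen) and Schwann cells (-0.00). At background in all 6 arrays were all 19 macrophage and leukocyte markers, 11 of 13 endothelial, 14 of 16 keratinocyte, 9 of 13 cartilage and bone, 9 of 10 Schwann and 8 of 14 adipocyte markers and 11 of 28 interferon response genes, whose medians therefore say little on expression. The mean of the TGFb response list (-0.04) and of the stress response list (-0.00) had the opposite sign to the median, as did the endothelial mean (0.06). The test directions of the stress response and endothelial lists were down without the block and up with it.

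The comparison of the EP4 antagonist with GHMT alone (n = 2 each) asked what the receptor contributes. Its 4 arrays are among the 6 of the inhibited and active arms, so that the same genes recur is largely built in. The genes ranked by the naming rule had to have 1 direction in both sets, so their agreement between the sets follows from the choice. Tnnt3, a muscle gene that this rule leaves out, was at 1.09 in set 1 and -1.12 in set 2. Among the named muscle genes, Myh6 was higher by 2.37 ± 0.35 (SE with the set as a block). Its difference was 1.68 in set 1, and at least 2.56-fold in set 2, where GHMT was at background. Actc1 was higher by 2.20 ± 0.30 (1.64 and 2.75), Myl1 by 1.94 ± 0.20 and Smyd1 by 1.78 ± 0.20. Myl7 was higher by 1.70 ± 0.21 and Tnni1, the slow skeletal troponin I, by 1.65 ± 0.20. Rab3b (2.96 ± 0.45), Col10a1 (2.30 ± 0.25), Rrad (1.74 ± 0.23), Flt1 (1.54 ± 0.20), Cspg4 (1.49 ± 0.20) and the growth factor Hbegf (1.36 ± 0.20) were higher too. Pde4b was lower (-3.33 ± 0.20), at least 5.99-fold in set 1, where the EP4 antagonist array was at background, and -3.43 in set 2. Mcpt8 was at -2.67, and lower by at least 1.16-fold in set 1, where the EP4 antagonist array was at background too. Fbln1 (-2.09 ± 0.23), Abi3bp (-1.95 ± 0.21), Tgfbi (-1.85 ± 0.24) and Mmp3 (-1.69 ± 0.24) were lower. So were Igfbp4 (-1.61 ± 0.23), Emb (-1.59 ± 0.20) and Il1r1 (-1.21 ± 0.20). Svs3b was at least 2.03-fold and Plac1 at least 1.26-fold lower, and Rtp4 was near background. Nppa, the atrial natriuretic peptide gene, was higher by 1.26 ± 0.20, Ryr2 by 0.54, Ptgs2 by 0.48 and Tnnt2 by 0.41, Col1a1 was at -0.58, Postn at -0.50 (-1.25 and 0.25), Hand2 at -0.37, Ptger4 at -0.23, Gata4 at 0.19, Il1b at -0.12, Mef2c at -0.11 and Tbx5 at 0.04 (-0.00 after quantile normalization). Of 70 genes at least 2-fold apart in both sets, 61 had the same direction (32 higher, 29 lower). The other 9 had opposite directions, where 35.1 would be expected if the directions were unrelated.

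No gene passed: limma called 0 without the block (144 at an unadjusted p under 0.05) and 0 with it (1243 unadjusted, smallest adjusted p = 0.0777, for Pde4b), against 8 with the block and a trend and robust prior (4 higher, 4 lower) and 31 with the block after quantile normalization. Without the block, 21 passed without GHMT replicate 1, 25 without EP4 antagonist replicate 1, 1 without GHMT replicate 2 and 16 without EP4 antagonist replicate 2; these fits compare arms from different sets. Camera called 15 lists (8 up, 7 down), 14 with the block, where cAMP and CREB targets were lost (0.208), 9 without EP4 antagonist replicate 1, and 0 with an estimated correlation or by fry. The sarcomere genes had a median of 0.70, and the 26 above background in at least 1 array one of 0.98 (26 positive; 0 of 37 over all genes, 16 with the block adjusted over the list alone; adjusted p = 0.216 with an estimated correlation). Theirs was the only list called whichever array was left out, and over the 10 alternatives the adjusted p of the called lists spanned 1.09e-22 to 0.990. The p53 targets had a median of 0.41 (adjusted p = 0.419 with an estimated correlation), collagen and matrix genes of -0.29 (0.419; -0.46 in set 1 and -0.02 in set 2), fibroblast identity genes of -0.28 (0.465) and cell cycle genes of -0.24 (0.572). With the block as well, these adjusted p were 0.655, and 0.686 for fibroblast identity. The list tests with an array left out were without the block, so the TTF sets lay unequally in the arms. Kept and ended calls therefore mix set differences with the dependence on an array. Leaving out GHMT replicate 1 ended the calls of p53 targets (adjusted p = 0.604), matrix genes (0.557), interferon genes (0.370), oxidative metabolism (0.198), cardiac transcription factors (0.0836), Wnt targets (0.630) and smooth muscle (0.955). Leaving out EP4 antagonist replicate 1 ended those of fibroblast identity (0.226), cell cycle (0.494), calcium handling (0.897), cAMP targets (0.378), inflammatory genes (0.776), interferon genes (0.317), hypoxia (0.281) and skeletal muscle (0.138). Without GHMT replicate 2, fibroblast identity (0.511), cell cycle (0.563), calcium handling (0.691), cAMP targets (0.944), inflammatory genes (0.887), hypoxia (0.153) and skeletal muscle (0.652) missed the threshold. Without EP4 antagonist replicate 2, p53 targets (0.516), Wnt targets (0.515) and smooth muscle (0.894) did. The inflammatory list was called down, but its 18 genes above background in at least 1 array had a median of -0.00 (9 positive, 9 negative). Mean and median differed in sign for macrophage (0.00 and -0.07), endothelial (0.09 and -0.01) and cartilage and bone markers (-0.07 and 0.02), and the TGFb response list (mean -0.01, median 0.00) was tested as up.

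The contrasts of 1 array against 1 within a set have no replicates of their own, and their differences are given without p. Only the counts of a fit over all 8 arrays, given with the TGFb and Wnt inhibitors, rest on a test. Diclofenac minus GHMT in set 1 asked what inhibiting prostaglandin synthesis does. Of the sarcomere genes, 18 of 37 were at least 2-fold higher and 1 lower with diclofenac (median 0.83), led by Myh6 (3.33), Csrp3, a Z-disc protein (2.45), Myl7 (2.17) and Ttn, the giant spring of the sarcomere (2.00). Nppa (1.82) and the calcium release channel Ryr2 (1.26) were higher as well, as were Col10a1 (3.54), Rab3b (2.40), Myl1 (2.22), Agt (2.18), Popdc2 (2.14) and Sh3tc1 (at least 2.01-fold). Pde4b (-2.44), Itm2a (-1.98), the matrix gene Dpt (-1.84), the secreted Wnt modulator Sfrp2 (-1.84), Mmp3 (-1.82), Tgfbi (-1.71), Fbln1 (-1.69), Ptprd (-1.62) and Il1r1 (-1.29) were lower. Sfrp2 lay on the other side (0.76) against the mean of both GHMT arrays, which mixes the TTF sets. Of 32 matrix genes, 6 were at least 2-fold lower and 1 higher (median -0.45), and 25 of all 32 were negative. Interferon response genes were slightly higher (median 0.37) and macrophage and leukocyte markers lower (-0.35, and 0.02 against the mean of both GHMT arrays), the latter with 0 of 19 above background. In all, 402 transcript clusters were at least 2-fold apart (232 higher, 170 lower), 94 of them at background in both arrays, 2 of these sarcomere genes. As a reference, the scaled difference between the EP4 contrasts of the sets gave 329.

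Adding PGE2 to diclofenac in set 1 asked whether the end product counters the inhibitor. Sarcomere genes were lower with PGE2 (median -0.70, 15 of 37 at least 2-fold lower), with Myh6 at -4.23, Myl7 at -3.11 and Actc1 at -2.70, and so were 4 of 25 genes of calcium handling (median -0.63), with Ryr2 at -1.90. This contrast reuses the diclofenac array with the opposite sign, so directions opposite to diclofenac minus GHMT come without any effect (r = -0.501 in simulation, -0.527 observed). Against GHMT, without that array, the sarcomere median with diclofenac plus PGE2 was -0.04 (18 positive, 19 negative), with Myh6 at -0.90, Myl7 at -0.94 and Actc1 at -1.05, and the matrix median was -0.30. Col10a1 (-3.94), Rab3b (-3.57), Spon1 (-3.28), Cited1 (-3.19), Smyd1 (-2.98), Myl1 (-2.80) and Agt (-2.53) were lower too. Targets of cAMP signalling were higher (median 0.28, 7 of 23 at least 2-fold higher and 3 lower), with Pde4b at 3.40, Nr4a3 higher by at least 2.21-fold and Nr4a2 at 1.25. Il1r1 was 2.04 higher, Ptger4, the EP4 gene, 1.10, and Ptgfr, the receptor of prostaglandin F, at least 2.82-fold. Hsd3b6, an enzyme of steroid synthesis (at least 6.26-fold), Ppbp (at least 3.91-fold), Mcpt8 (at least 3.38-fold), Chl1 (at least 2.78-fold), Sod3, an extracellular superoxide dismutase (3.10), Emb (2.87), Erv3 (2.78) and Prg4 (2.60) were higher. Fibroblast identity (0.46), cell cycle (0.50), inflammatory (0.27), prostanoid (0.26) and hypoxia genes (0.24) had positive medians outside the range of random lists, as did macrophage and leukocyte markers (0.23, with 0 of 19 above background). The p53 targets (-0.34) and the stress response list (-0.24) had negative ones. In all, 479 were at least 2-fold apart (188 higher, 291 lower), 71 of them at background in both arrays.

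The EP4 antagonist was compared with GHMT in each set. In set 1, 17 of 37 sarcomere genes were at least 2-fold higher and 1 lower (median 0.80), with Csrp3 at 2.95 and Myoz2 at 1.92, along with Popdc2 (1.98), Map3k7cl (1.89), Msln (1.88) and Ildr2 (1.84). Dpt (at least 4.24-fold), Pde4b (at least 5.99-fold), Sfrp2 (-2.11, and 0.49 against the mean of both GHMT arrays), Mmp3 (-2.02), Ifi211 (-1.92) and Igfbp3 (-1.70) were lower, and the interferon list had a median of -0.32. In set 2, 9 of 37 sarcomere genes were at least 2-fold higher (median 0.56), and Stmn2, a neuronal microtubule regulator (3.99), Rab3b (3.95), Ramp1 (3.04), Adamts5 (2.69), Igfbp2 (2.43), Ano1 (2.22) and Ifit3 (at least 5.15-fold) were higher. Hsd3b6 (at least 11.2-fold), Tnn (-3.70), Mcpt8 (-3.56), Erv3 (-3.13), Cxcl14 (-2.82), Gpr50 (at least 5.06-fold), Ptgfr (at least 4.92-fold) and Il11 (at least 1.92-fold) were lower. The counts at least 2-fold apart were 354 in set 1 (180 higher, 174 lower) and 608 in set 2 (286 higher, 322 lower), 78 and 187 of them at background in both arrays. In set 2, the median of hypoxia genes was -0.39 and that of calcium handling genes 0.20, but 0.18 and -0.07 against the mean of both GHMT arrays. Nppa in set 1 was higher by 1.15 against the GHMT array of the set and at -0.42 against that mean. The mean mixes the TTF sets, and Nppa in GHMT was at 12.26 in set 1 and 15.4 in set 2. Within set 2, Nppa was higher by 1.37.

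Genes chosen in set 2 were followed in set 1, whose arrays did not enter the choice. The 100 genes highest with the EP4 antagonist in set 2 (median 1.51) had medians in set 1 of 0.44 with diclofenac (79 positive), 0.38 with the EP4 antagonist (71 positive) and -0.86 on adding PGE2 to diclofenac (86 negative). The 100 lowest (median -1.67) had medians of -0.34, -0.46 and 0.67 in these contrasts. Of random lists matched on level, 95% lay between -0.09 and 0.10 in each case. Conversely, the 100 genes highest with the EP4 antagonist in set 1 had medians in set 2 of 0.43 with the EP4 antagonist, 0.20 with the TGFb inhibitor and 0.32 with the Wnt inhibitor, and the 100 lowest of -0.33, -0.16 (0.06 for 50 genes) and 0.25. Across all genes, which are not independent replicates, the EP4 antagonist contrasts of the sets correlated with Pearson's r of 0.108 and Spearman's rho of 0.0501, and PGE2 addition in set 1 and the EP4 antagonist in set 2 with -0.229 and -0.101. These were 2 of 9 such pairs; the others ran from -0.223 to 0.106. Contrasts that share a control array correlate without any effect, at about 0.50 in simulation. Those observed were 0.655 for diclofenac and the EP4 antagonist in set 1, and in set 2 0.289 for the EP4 antagonist and the TGFb inhibitor, 0.362 for the EP4 antagonist and the Wnt inhibitor and 0.553 for the TGFb and Wnt inhibitors. Their covariances exceeded the simulated ones by 0.0407, 0.0143, 0.0256 and 0.0970. The simulation used each gene's moderated spread, and a larger spread would raise the simulated covariance. No shared effect is therefore read from these excesses.

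**Figure D2:**
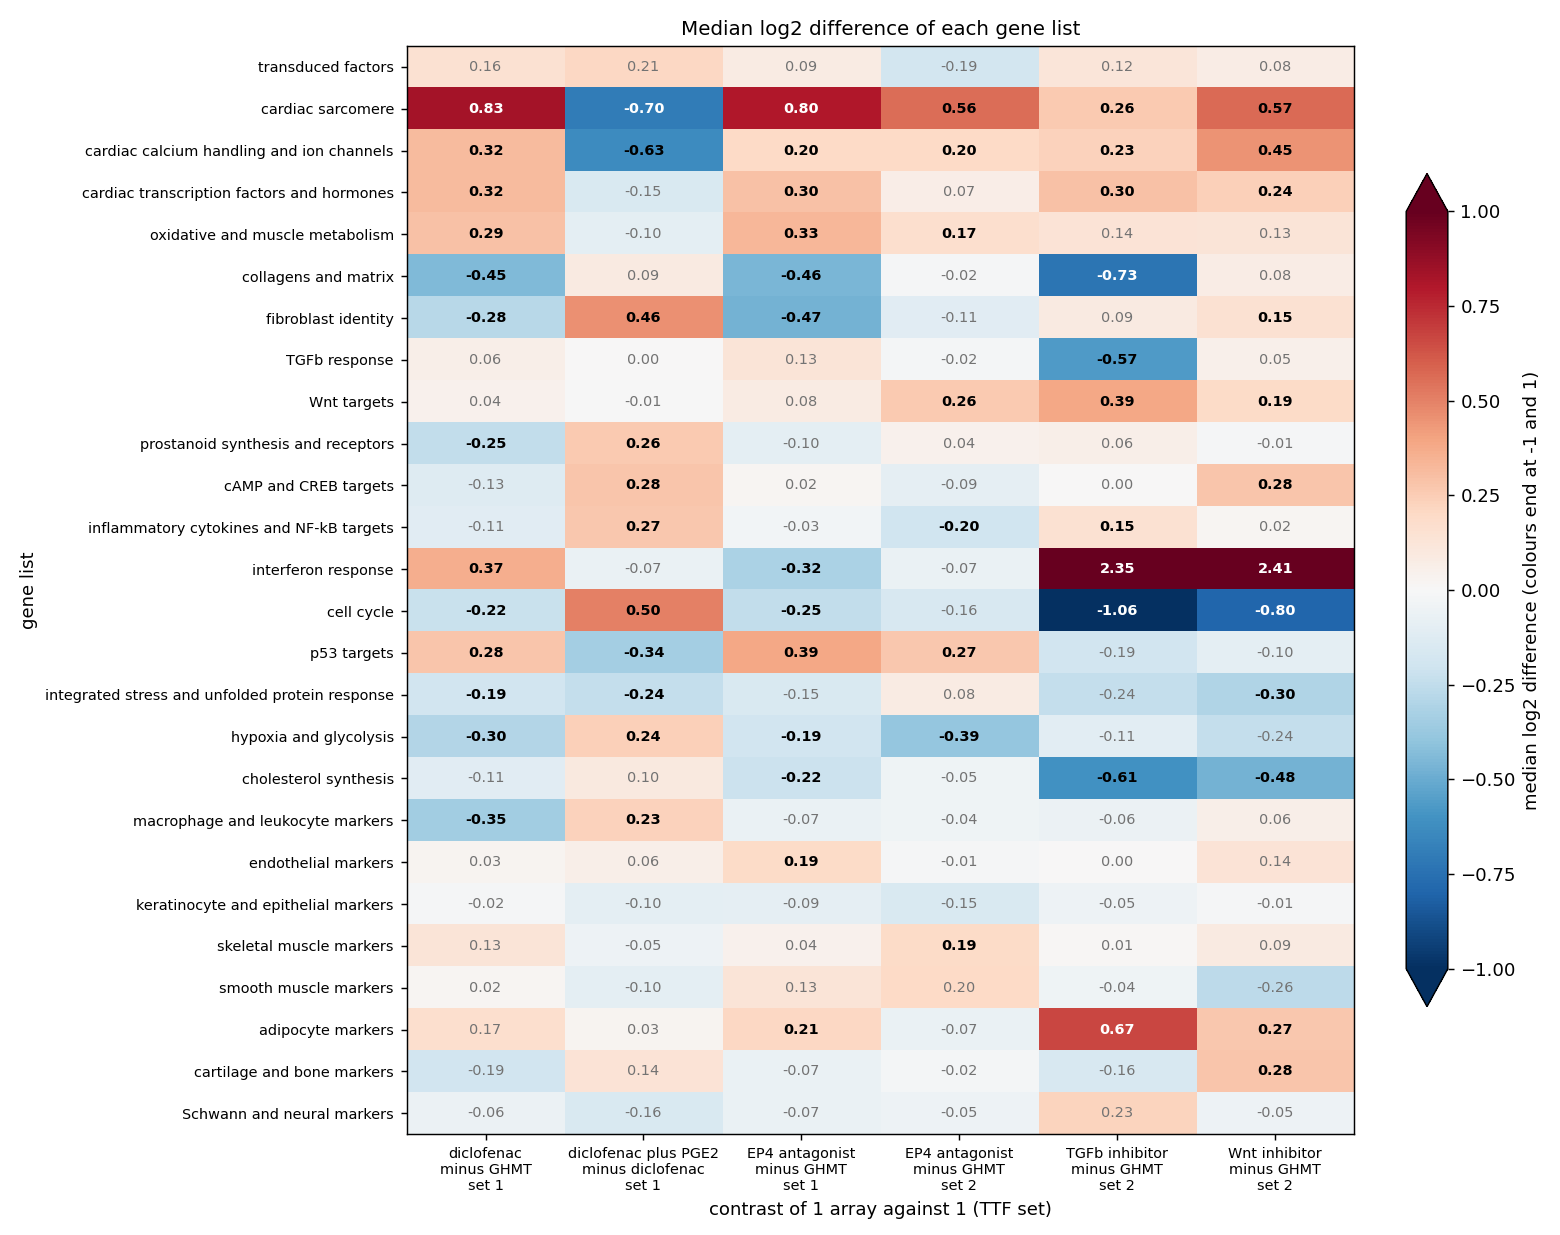
Median log2 difference of each of the 26 gene lists (vertical axis) in the 6 contrasts of 1 array against 1 (horizontal axis), with the value printed in each cell, in bold where it lay outside the central 95% of 10000 random lists matched on mean level. The sarcomere median was positive in each contrast against GHMT (0.26 to 0.83) and -0.70 on adding PGE2 to diclofenac, and the interferon median was highest with the TGFb inhibitor (2.35) and the Wnt inhibitor (2.41).

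The TGFb inhibitor in set 2 was compared with GHMT as another way to enhance reprogramming. TGFb response genes were lower, 13 of 27 at least 2-fold (median -0.57), with Lrrc15 lower by at least 8.56-fold, Pmepa1, a feedback inhibitor of the pathway, at -3.88 and Tgfbi at -3.23. Of 32 matrix genes, 12 were at least 2-fold lower and 1 higher (median -0.73), among them Col5a2 (-3.06), Col1a2 (-2.81), Postn (-2.64) and Fn1 (-2.50). Cell cycle genes were lower, 18 of 32 at least 2-fold (median -1.06), with Plk1 at -1.93. Interferon response genes were the most elevated list, with all 28 positive and 21 at least 2-fold higher (median 2.35); Ifit1 was higher by at least 51.4-fold, Ifit3 by at least 38.4-fold, Irf7 by at least 31.2-fold and Oasl2 by at least 29.9-fold. Among sarcomere genes, 11 were at least 2-fold higher and 2 lower (median 0.26), with Myl7 at 3.43, Myl4 at -1.20 and Myh6 higher by at least 1.98-fold, and Myl1 was at 6.14. Svs3b (5.48), Ifi207 (5.25), Ccn3 (4.98) and Ly6c1 (4.69) were higher, and Erv3 (-4.94), Pdlim3 (-4.63), Cthrc1 (-3.99), Fam20a (-3.94), Ppbp (-3.65), Ncam1 (-3.57), Pappa (-3.52), Serinc2 (-3.39) and Ptgs2 (-2.54) lower. In all, 1189 were at least 2-fold apart (629 higher, 560 lower), 228 of them at background in both arrays, among them 3 sarcomere and 3 interferon genes. A limma fit over all 8 arrays, with 1 residual degree of freedom and the lone array assumed to vary like the others, called 103 (72 higher, 31 lower; 12 from the interferon list).

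The Wnt inhibitor in set 2 was compared with GHMT in the same way. Axin2, a feedback target of Wnt signalling, was lower by at least 1.95-fold and Apcdd1, a Wnt antagonist, was at -1.83, while the 22 Wnt targets as a list were not lower (median 0.19; 3 at least 2-fold higher, 2 lower). Sarcomere genes were higher, 10 of 37 at least 2-fold with 2 lower (median 0.57), with Actc1 at 3.02, Myl7 at 2.66, Myom1 at 2.29 and Csrp3 at -2.11. Genes of calcium handling and ion channels were higher (median 0.45, 6 of 25 at least 2-fold), with Ryr2 at 2.00 and the pacemaker channel Hcn4 at 1.65. Interferon response genes were higher, 19 of 28 at least 2-fold (median 2.41), with Ifit3 higher by at least 65.1-fold, Oasl2 by at least 60.7-fold, Ifit1 by at least 52.5-fold, Irf7 by at least 49.7-fold and Usp18 by at least 48.6-fold. Cell cycle genes were lower (median -0.80, 7 of 32 at least 2-fold). Stmn2 (4.50), Ifi207 (4.21) and Sfrp2 (4.19) were higher, and Ppbp (-4.44), Peg10 (-3.53), Tnn (-3.30), Mcpt8 (-2.57), Cyp1b1 (-2.36), Hhip (at least 2.99-fold) and Ptgs2 (-1.25) lower. Mcpt8 (0.47) and Ptgs2 (0.32) were higher against the mean of both GHMT arrays, which mixes the TTF sets. In all, 909 were at least 2-fold apart (561 higher, 348 lower), 224 of them at background in both arrays, among them 2 sarcomere genes and 1 interferon gene. The fit over all 8 arrays called 27 (all higher, 11 from the interferon list). That fit called 0 in the contrasts of diclofenac (974 at an unadjusted p under 0.05), PGE2 addition (1041) and the EP4 antagonist (1243).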

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

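The tests of explanations in this part were chosen only after the result was seen, apart from the counts of splits of the 6 arrays. In 5 named genes the EP4 antagonist contrasts of the TTF sets were measured in opposite directions, by 2-fold or more each; whether the sets differ was not tested, since each holds 1 array per arm. Pcdh19 was at -1 in set 1 and 1.71 in set 2, and Tnnt3, a fast skeletal troponin T, at 1.09 and -1.12, each with 4 of 4 arrays above background. Brinp1 was at -1.17 and 1.09 and Itgb3bp at -1.11 and 1.12, but the EP4 antagonist array of set 1 was at background, so that in set 1 Brinp1 was lower by at least 1.24-fold and Itgb3bp has no bound. Myl2, the ventricular myosin light chain, was at -1.11 and 1.69 with 0 of 4 arrays above background, so its values say nothing on expression.

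Interferon response genes were higher with the TGFb inhibitor (median 2.35) and the Wnt inhibitor (2.41) than with GHMT. Transcripts of Hand2 and Tbx5 were not 1.5-fold higher: the larger of their differences was 0.25 and 0.04. Untransduced cells were not among the samples, so whether these clusters read the transduced factors is not known. A dose of the factor viruses at least 1.5-fold higher therefore stays open. RNA from leukocytes is argued against, with 0 and 1 of 19 markers above background (Lyz2 with the Wnt inhibitor). A difference in culture or array handling shared by these arrays cannot be told apart from the inhibitors, because there was 1 array per inhibitor. An effect of the inhibitors themselves stays open and untested.

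The GHMT arrays of the sets were at least 2-fold apart in 3036 transcript clusters. A different overall scale of the sets is argued against as the whole cause: after quantile normalization 2124 were left, against at most 539 in a contrast of PGE2-EP4 drugs within a set. Quantile normalization equalizes only the distributions of the arrays. Offsets of single genes, should the sets have been normalized separately, were therefore not tested. Different fibroblast preparations or days cannot be told apart, since there were 2 sets with 1 GHMT array each. No biological explanation was tested.

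Splits of the 6 arrays of the inhibited and active arms into 3 and 3 number 10, too few for a share under 0.05. Without the block the real split gave 0 genes by limma (469 at an unadjusted p under 0.05), all 10 splits gave as many or more, and the highest other gave 33. That split sets GHMT, diclofenac and the EP4 antagonist of set 1 against diclofenac plus PGE2 and both arrays of set 2. It partly follows the TTF sets, and with the set as a block it gave 0. The other splits with both arrays of set 2 in 1 arm gave 0 without the block as well, so the cause of the 33 stays open. With the block the real split gave 84, 1 of 10 with as many, and the highest other gave 0. Like the real split, 6 of the 10 part the arrays of set 2, and the highest other of these gave 0 with and without the block; the remaining 4 put both arrays of set 2 in 1 arm, so there the set is partly confounded with the arms.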

How the results depend on the processing

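The combinations of the block with other settings, the tests on set 1 arrays alone (0 genes past the threshold) and the mean of both GHMT arrays as control for single genes and lists were chosen only after the results were seen. The set 1 test is the same fit as that with the block without either array of set 2. Where no cause is named, the cause was not tested. For the EP4 antagonist against GHMT, 0 genes passed without the block and with it; with the block, 31 passed after quantile normalization, 8 with a trend and robust prior and 1 at an adjusted p under 0.1. Lists past the threshold fell from 15 to 0 with an estimated correlation, 0 with the replicate block and an estimated correlation and 0 with fry. For the inhibited against the active arm, 0 genes passed without the replicate block (1 at an adjusted p under 0.1) and 84 with it, 143 with the block, a trend and a robust prior, and 157 with the block at an adjusted p under 0.1. Lists went from 14 to 1 with an estimated correlation, 0 with the replicate block and an estimated correlation, and 1 with fry. The block ended the call of cAMP and CREB targets with the EP4 antagonist and no other list call. Tbx5 with the EP4 antagonist turned to -0.00438 after quantile normalization, with and without the block. Among named genes and called lists of the EP4 antagonist over all settings, 363 gene values were kept on their side of the threshold, 48 passed it and 19 turned; for lists these were 74 kept, 65 lost and 11 turned. For the inhibited against the active arm they were 598, 118 and 22 for genes and 110, 56 and 2 for lists.

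Leaving out 1 array without the block leaves the TTF sets unequal between the arms, so by construction set differences enter. Without 1 array the EP4 antagonist comparison gave 1 to 25 genes and 9 to 15 lists, and these genes ranged over 0: Mcpt8 -5.70 to 0.37, Gata4 -0.02 to 0.40, Hand2 -0.96 to 0.22, Mef2c -0.76 to 0.55, Tbx5 -0.28 to 0.35, Ptgs2 -1.48 to 2.43, Ptger4 -0.73 to 0.28, Nppa -0.42 to 2.94, Ryr2 -0.065 to 1.14, Postn -1.53 to 0.53 and Il1b -0.69 to 0.46. Adjusted p ranged from 1.87e-07 to 0.897 for calcium handling, 7.18e-12 to 0.511 for fibroblast identity, 0.00145 to 0.630 for Wnt targets, 4.16e-05 to 0.944 for cAMP targets, 1.01e-05 to 0.887 for inflammatory genes, 9.41e-08 to 0.563 for cell cycle, 8.07e-10 to 0.281 for hypoxia and 0.000906 to 0.955 for smooth muscle. The inhibited against active comparison gave 0 to 3 genes without the block and 0 to 192 with it. Its genes that ranged over 0 were Gata4 -0.10 to 0.17, Hand2 -0.60 to 0.10, Mef2c -0.42 to 0.38, Tbx5 -0.25 to 0.17, Ptgs2 -1.23 to 1.13, Nppa -0.0283 to 1.79, Postn -0.79 to 0.24 and Il1b -0.51 to 0.0617. Adjusted p ranged from 0.00179 to 0.979 for Wnt targets and 6.91e-07 to 0.485 for hypoxia.

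In the contrasts of 1 array against 1, the counts at 1.5-fold were 2413 for diclofenac, 2315 for PGE2 addition, 2303 and 2845 for the EP4 antagonist in sets 1 and 2, 3669 for the TGFb inhibitor and 3706 for the Wnt inhibitor, by construction more than at 2-fold. The limma fit over all 8 arrays, with the replicate block and 1 residual degree of freedom, called 0, 0, 0, 0, 103 and 27 in these contrasts. Against the mean of both GHMT arrays, which mixes the sets by construction, 608 were apart for diclofenac and 625 for the EP4 antagonist in set 1. With that control these turned: macrophage markers 0.02 and Sfrp2 0.76 with diclofenac, Sfrp2 0.49 and Nppa -0.42 with the EP4 antagonist in set 1, calcium handling -0.065 and hypoxia 0.18 in set 2, and cartilage and bone markers -0.035, Mcpt8 0.47 and Ptgs2 0.32 with the Wnt inhibitor. Centring left all 205 named gene values and 68 list medians within the spread, and quantile normalization all 205 and 64, with 4 medians moved further. The filter on level moved 22 of the 68 medians. The mean of both GHMT arrays as control moved 117 gene values and 36 medians, turned 5 and 4, and left 50 and 17 within the spread. For followed genes, 50 and 200 per direction gave, for those highest in set 2, 0.64 and 0.25 with diclofenac, -1.15 and -0.51 on adding PGE2 and 0.71 and 0.18 with the EP4 antagonist. Those lowest in set 2 gave -0.24 (200) with diclofenac, 1.41 and 0.41 on adding PGE2 (0.79 with the filter on level) and -0.26 (200) with the EP4 antagonist. Those highest in set 1 gave 0.62 and 0.30 with the EP4 antagonist and 0.65 and 0.18 with the Wnt inhibitor. Those lowest in set 1 gave -0.43 with the EP4 antagonist (filter), 0.06 with the TGFb inhibitor (50) and 0.71 and 0.06 with the Wnt inhibitor. Signal over background limits what can be seen: 43.7% to 45.7% of the transcript clusters lay above it.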

Other observations

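The tests on diclofenac plus PGE2 against GHMT were chosen only after the result was seen. The prostanoid list as a whole lay inside the range of random lists with both inhibitors of set 2 (median 0.06 with the TGFb and -0.01 with the Wnt inhibitor), and single members lay apart from GHMT. With the TGFb inhibitor, Ptger3, the EP3 receptor of PGE2, was at 2.38 and Slco2a1, the prostaglandin transporter, at 2.29 against GHMT, while Ptgs2 was at -2.54. With the Wnt inhibitor, Hpgd, which inactivates prostaglandins, was at 2.30 and Ptgs2 at -1.25. Adipocyte markers had positive medians with both, 0.67 for the TGFb inhibitor and 0.27 for the Wnt inhibitor. Of 14 markers, 4 were at least 2-fold higher and 0 lower with the TGFb inhibitor, and 3 higher and 1 lower with the Wnt inhibitor. In the 6 arrays of the inhibited and active arms, which do not include those of these inhibitors, 8 of the 14 lay at background throughout. Of the markers at least 2-fold apart, 1 with the TGFb inhibitor and 0 with the Wnt inhibitor were at background in both arrays. The other markers were not counted in this way, so how far the medians reflect expression is not settled. Lpl, a lipase that releases fatty acids, was at 2.73 and 2.50. Pparg, the regulator of fat cell formation, was higher by at least 1.94-fold and 2.34-fold. Cholesterol synthesis genes were lower with both (median -0.61 and -0.48), with Dhcr7 at -1.41 for the TGFb inhibitor and Mvd at -1.21 for the Wnt inhibitor.

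Diclofenac plus PGE2 was also compared with GHMT in set 1 (401 at least 2-fold apart, 198 higher and 203 lower; 1 array each). Hsd3b6 (at least 7.52-fold), Sod3 (3.31), Ptgfr (at least 3.39-fold), Cd24a (2.24), the peptide hormone gene Cck (2.14), Ppbp (2.14) and the collagenase Mmp13 (1.95) were higher. Ccn3 (-2.34), Plagl1 (-2.31), Gas2 (-2.26), Aspn (-1.99), Mfap4 (-1.94) and Spon1 (-1.86) were lower.

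The 100 genes lowest with the EP4 antagonist in set 2 had a median of 0.47 in diclofenac plus PGE2 minus GHMT (73 positive), outside the range of random lists (-0.07 to 0.11). The same genes lay on the other side of the GHMT array of set 1 with diclofenac (-0.34) and the EP4 antagonist (-0.46). Genes chosen as lower with the EP4 antagonist could lie there whether or not that array was unusual. An unusual GHMT array in set 1 therefore stays open. More PGE2 signalling with added PGE2 than in the vehicle cultures stays open and untested: the value of 0.47 is the pattern itself, no dose is given, and there was 1 array per arm.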
